A study of Homo sapiens with 29 samples.

How the data were processed

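Whole-tumour RNA from 29 HT-29 xenografts in 6 groups (control 5, 5-FU 4 and 5 of each other group) was prepared, per the labels, with ISOGEN, depleted of ribosomal RNA with Ribo-Zero Plus and made into libraries with the TruSeq stranded mRNA kit. The FPKM values were deposited in 1 table, made by the authors with FastQC, Trimmomatic, HISAT2, SAMtools and featureCounts on GRCh38.p5. Versions, the annotation, the strand setting and the handling of mouse reads are not given in the sources used here. Rows carry gene names only: 2087 of 60658 rows have a name that occurs more than once and were kept apart, and 27693 rows are 0 in every library. Gene lengths, types and positions were taken from GENCODE release 29, whose build may not be the one the authors used, and 79.1% of the tested rows had a length.

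The libraries were grouped by the labels. Read depth cannot be taken from FPKM, so precision was read from the spread between libraries: the limits of the 95% interval of a log2 change lay 0.49 to 0.52 to each side of it in the median gene, or 0.72 for the interactions. Values were used as log2(FPKM + 1), rows with at least 0.5 FPKM in at least 4 libraries were tested (17628), and one linear model over all 29 libraries was fitted with limma 3.58.1 in R 4.3.3, with a trended and robust prior. In all, 11 comparisons and 2 interactions were tested, and p-values were adjusted by Benjamini-Hochberg within each, with a threshold of 0.05. The other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

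Gene lists, 36 in all, were fixed before the files were seen and tested with camera in limma at a preset correlation of 0.01, adjusted over the 36. Camera with an estimated correlation and fry were run as alternatives, and each member was also adjusted over its list alone. The lists are those whose results the report gives for 5-FU against control. A list score is the mean deviation of its genes from their mean over the 29 libraries. Named genes were chosen by a rule fixed in advance. It took up to 8 of the largest rises and falls among genes past the threshold with a mean of at least 1 FPKM in one group, and up to 4 members of smallest adjusted p from each list that passed or held at least 3 members past the threshold. It always took KDM5A, KDM5B, KDM5C, TYMS, CDKN1A, MDM2, MYC and EPCAM. Where fewer than 3 genes passed, the 3 smallest unadjusted p in each direction were named as not past the threshold. Other genes are said to have been chosen after their values were seen, and a few genes that the rule took are not reported here.

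Total FPKM was split at 1e6 and compared between the 14 libraries given 5-FU and the 15 others by 2-sided permutation with 100000 resamples and by Fisher's exact test. Short and long protein-coding genes (3076 each) lay at or below 3122 and at or above 7397 nucleotides of merged annotated exons. Scores of lists were compared between the 2 inhibitors by exact 2-sided permutation over 252 arrangements, and between 5-FU-treated and other libraries by exact permutation within the libraries above and below the division. For likeness of the compounds, 1000 simulated pairs of unchanged groups and 20 splits of the controls were used. Counts were compared over 100 splits of the same libraries, the real one included. On simulated changes of log2 1, 47.8% were recovered for 5-FU against control, 38.8% for JB-157 against control, 46.3% for JB-157+5-FU against 5-FU and 49.3% for JB-157 against JB-161 (67 genes each), and of log2 2, 98.5%, 89.4%, 89.4% and 89.4% (66 genes each).

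Alternatives fixed in advance were the pseudocount, the filter, TPM and median-ratio scaling, fits of only the groups compared, the replicate number as a block, array weights and each library left out. Log2 total FPKM as a covariate and fits within libraries above or below 1e6 total FPKM were added after the totals were seen, and list tests with each library left out after the lists were seen. No library was left out of the main analysis.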

Results

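HT-29 is an established human colorectal adenocarcinoma line. Here it was grown under the skin of NOD/SCID mice, which lack working lymphocytes, and RNA was taken from the tumours. Mice were injected into the peritoneum on days 4 and 7 with 0.2 mL of JB-157 or JB-161 at 6.69 mg/kg or of 5-FU at 100 mg/kg. Others received one of the JB compounds together with 5-FU. 5-FU is fluorouracil, a pyrimidine analogue that blocks thymidylate synthase and is misincorporated into RNA and DNA. The labels call JB-157 and JB-161 inhibitors of KDM5B, a demethylase that removes methyl groups from lysine 4 of histone H3, and do not state doses separately for the combinations. Controls received the solvent DMSO. The deposited table held 29 libraries, 5 from control, 4 from 5-FU, 5 from JB-157, 5 from JB-161, 5 from JB-157+5-FU and 5 from JB-161+5-FU, with 1 FPKM value per library for each of 60658 rows. The labels do not say that the libraries of a group came from separate animals, so each p-value measures only the spread between these samples, which may be technical. Read depth is unknown, because the values are FPKM. Of the rows, 17628 had at least 0.5 FPKM in at least 4 libraries and were tested on the scale log2(FPKM + 1), on which a fold change understates the change of a low gene. Genes are given by symbol as in the table, and a log2 change is followed by its standard error after the sign ±, while a mean FPKM is followed by its SD.

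Total FPKM and the balance of short and long genes moved with 5-FU across the study. The total, in units of 1e6 FPKM, was 0.786 ± 0.312 in the 14 libraries from tumours that had received 5-FU and 1.43 ± 0.349 in the 15 others (2-sided permutation test with 100000 resamples, p = 9e-05). By group, the mean total was 1.42 ± 0.455 in control (n = 5), 0.607 ± 0.0648 in 5-FU (n = 4), 1.40 ± 0.135 in JB-157, 1.47 ± 0.444 in JB-161, 0.790 ± 0.222 in JB-157+5-FU and 0.924 ± 0.456 in JB-161+5-FU (n = 5 each). Protein-coding genes in the shortest quartile by transcript length, minus those in the longest, gave a mean log2 deviation of -0.345 ± 0.383 in the 14 treated and 0.322 ± 0.264 in the 15 other libraries (2-sided permutation test, p = 7e-05). A total below 1e6 FPKM was found in 12 of the 14 treated and 2 of the 15 other libraries (Fisher's exact test, 2-sided p = 0.000145). The exceptions were JB-161+5-FU 1 (1.74) and JB-157+5-FU 4 (1.17) among the treated, and control 5 (0.865) and JB-161 3 (0.787) among the others. Mitochondrial transcripts took 5.24% to 30.4% of the total and the 49 ribosomal protein genes 13.3% to 21.2%.

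**Figure D1:**
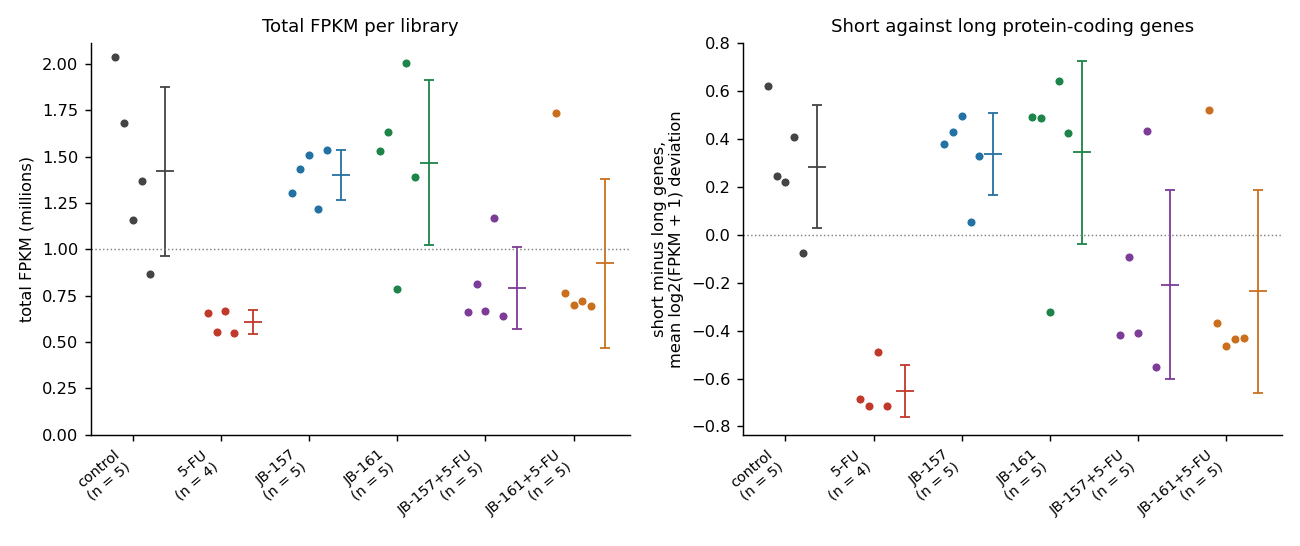
Total FPKM per library in units of 1e6 (left) and the mean log2(FPKM + 1) deviation of short minus long protein-coding genes (right), by group. Points are libraries, the bar beside them is the mean with its SD, and the dotted lines mark 1e6 FPKM and 0; 12 of the 14 libraries that had received 5-FU lie below 1e6.

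5-FU alone was compared with control first, since it is the reference drug of the design. REG4, a secreted lectin of goblet and enteroendocrine cells, fell from 846 ± 361 FPKM in control to 53.3 ± 31.8 in 5-FU (n = 5 and 4, log2 change -3.98 ± 0.48, limma with Benjamini-Hochberg adjustment, adjusted p = 9.69e-05), and each 5-FU library lay below each control. PHGR1, a transcript of differentiated gut epithelium, fell by 3.48 on the log2 scale (adjusted p = 0.000661). CDX1, a transcription factor of the intestinal epithelium, fell by 2.88. FABP1, the fatty acid binding protein of liver and gut, fell from 14.6 ± 4.34 to 3.43 ± 1.33 FPKM (log2 change -1.82 ± 0.24, adjusted p = 0.000149). Interferon-stimulated transcripts were higher: IFIT1, an RNA-binding antiviral protein, rose from 1.88 ± 0.756 to 11.0 ± 7.25 FPKM (log2 change 1.89 ± 0.31, adjusted p = 0.000573), and XAF1 had a log2 change of 1.93 ± 0.32. Among the largest rises were the golgin genes GOLGA8B (3.16) and GOLGA8A (2.43), which are close copies and may share reads, NFKBIZ (2.92), an atypical inhibitor of NF-kB, BTAF1 (2.67), NKTR (2.46), Six3os1_2 (2.28) and OGT (2.30), which attaches N-acetylglucosamine to proteins. Among the largest falls were the spliceosomal RNA genes RNU2-2P (-4.48) and RNU4-2 (-4.13), ATP5D (-3.24), a subunit of ATP synthase, and TM4SF5 (-3.21). MT-TY was listed at 0 in the 4 5-FU libraries and at 1439, 869.9, 747, 0 and 295 FPKM in controls 1 to 5. RNA5S6 was listed at 0 and at 32.1, 31, 13.3, 33.3 and 0 in the same order. HOTAIRM1_1 was listed at 9.84, 15.8, 4.68 and 1.59 in 5-FU and at 0 in the 5 controls.

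In all, 8066 of 17628 genes passed, 3842 higher and 4224 lower in 5-FU. Rescaling to TPM moved the median log2 change of all genes by 0.77 and the split to 10197 higher and 1028 lower, so gene lists are described relative to the median of all genes. With log2 total FPKM as a covariate, a model chosen after the totals were seen, 4 genes passed. Among the 8066 the median size of the log2 change went from 0.98 to 0.27 and the median standard error from 0.28 to 0.25, so these calls ended because the changes shrank. The 4 were REG4 (log2 change -2.22 ± 0.38, adjusted p = 0.0452), FABP1 (-1.69 ± 0.32, adjusted p = 0.0465), HOPX (-1.95), a homeodomain-only protein, and LRRC6 (1.39), both named after their values were seen.

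List medians are relative to the median of all genes, with the value under TPM where it moved by over 1.5 times or turned. Genes of the sterol synthesis list, the mevalonate pathway and its targets, fell after 5-FU: 1 of 25 rose, 15 fell and 9 did not pass (1 and 15 adjusted over the list alone, median -1.08, -0.67 with TPM, camera adjusted p = 9.13e-05, but 0.618 with an estimated correlation). MVD, which makes isopentenyl diphosphate, went from 122 ± 39.3 to 25.9 ± 9.61 FPKM (log2 change -2.17 ± 0.37, adjusted p = 0.00061), and MVK (-1.99) fell too. In the goblet and secretory list, 0 of 20 rose, 14 fell and 6 did not pass (0 and 15 adjusted over the list alone, median -1.16, camera adjusted p = 4.76e-05, but 0.618 with an estimated correlation). SPINK4 (-2.78), TFF1 (-2.31), a trefoil peptide of mucus, and the mucin MUC5AC (-1.81) fell beside REG4. For the interferon response list, 25 of 36 rose, 3 fell and 8 did not pass (26 and 4 adjusted over the list alone, median 1.05, camera adjusted p = 1.58e-06, but 0.618 with an estimated correlation). IFIT3 (1.66) and the RNA sensor DDX58 (1.44) rose with it, yet the list score per library ran from -0.02 in 5-FU 1 to 1.30 in 5-FU 4, with 0.77 in 5-FU 2 and 0.22 in 5-FU 3. Of ribosomal protein genes, 0 of 49 rose, 43 fell and 6 did not pass (0 and 44 adjusted over the list alone, median -1.39, camera adjusted p = 8.3e-12, but 0.618 with an estimated correlation). RPL35 had a log2 change of -2.45. On the oxidative phosphorylation list, 0 of 30 rose, 24 fell and 6 did not pass (2 and 24 adjusted over the list alone, median -1.19, -0.75 with TPM, camera adjusted p = 1.58e-06, but 0.618 with an estimated correlation). CYC1 (-2.05) and UQCRC1 (-1.87), parts of respiratory complex III, fell. Glycolysis genes followed: 0 of 20 rose, 11 fell and 9 did not pass (0 and 11 adjusted over the list alone, median -0.85, -0.43 with TPM, camera adjusted p = 0.00225, but 0.618 with an estimated correlation). ALDOC (-1.88), PFKL (-1.84) and GAPDH (-1.65) fell. Among MYC targets, 1 of 29 rose, 17 fell and 11 did not pass (2 and 17 adjusted over the list alone, median -0.62, -0.19 with TPM, camera adjusted p = 0.0093, but 0.618 with an estimated correlation). With TPM the camera adjusted p was 0.118. SRM, spermidine synthase, had a log2 change of -2.56. Before subtraction of the all-gene median, TPM turned the list medians of oxidative phosphorylation (-1.15 to 0.02), sterol synthesis (-1.05 to 0.10), glycolysis (-0.82 to 0.33) and MYC targets (-0.58 to 0.58).

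**Figure D2:**
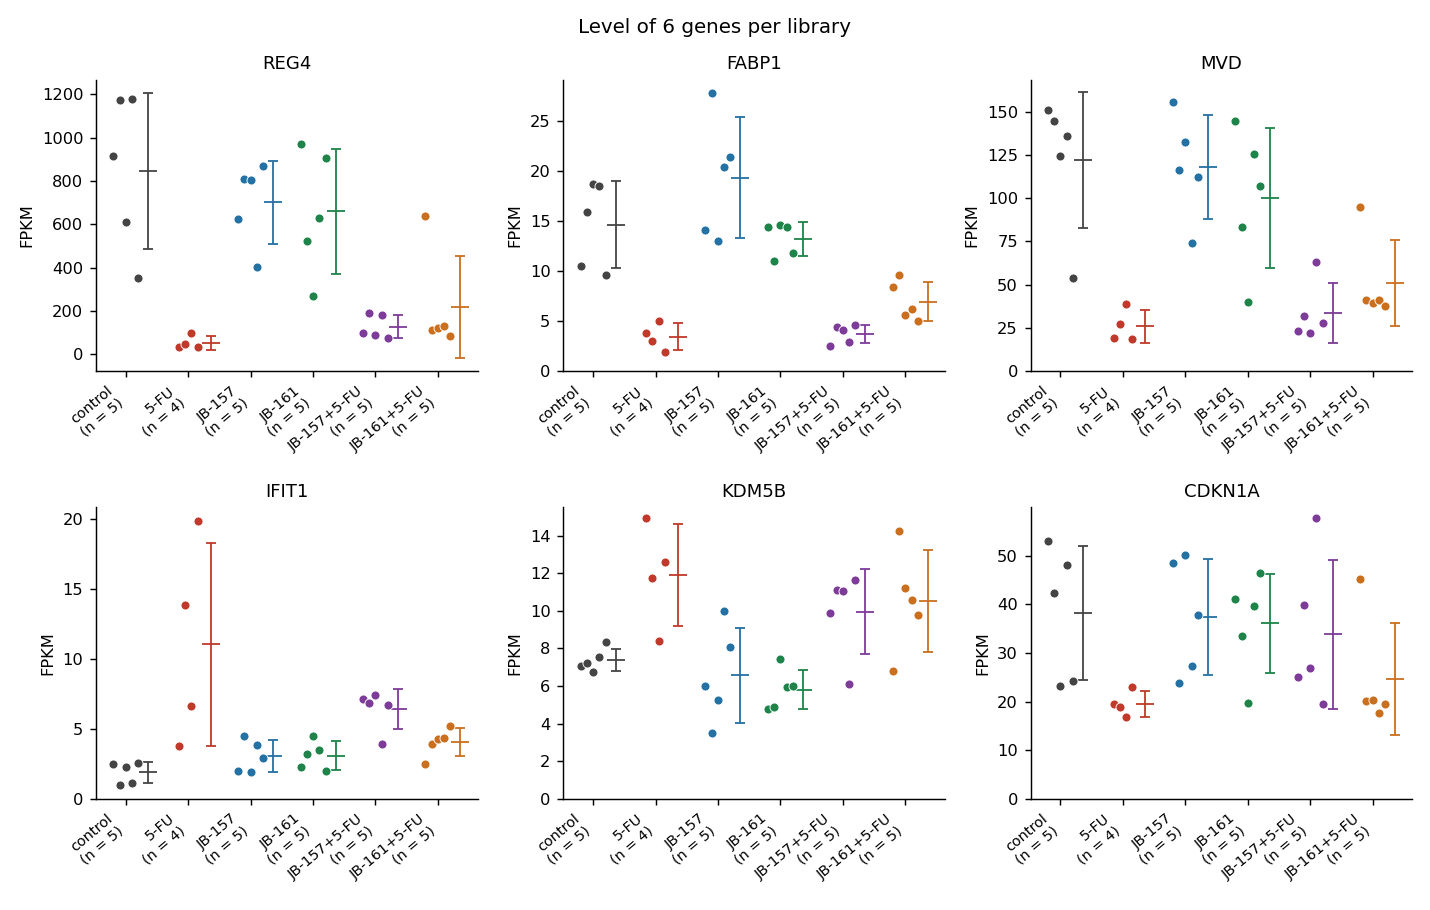
FPKM of REG4, FABP1, MVD, IFIT1, KDM5B and CDKN1A in each library, by group. Points are libraries and the bar beside them is the mean with its SD; REG4 averages 846 ± 361 FPKM in control and 53.3 ± 31.8 in 5-FU, and the points of JB-161+5-FU 1 lie with the groups not given 5-FU for REG4.

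The remaining lists did not pass as lists after 5-FU, although single members did. Brackets give the counts adjusted over the list alone (alone) and the camera adjusted p. Enterocyte differentiation missed the threshold with 2 of 22 members rising and 11 falling (alone 2 and 11, adjusted p = 0.0507), CEACAM7 (1.63) going against CDX1 and FABP1. The p53 targets had 7 of 26 members rising and 11 falling (alone 8 and 11, adjusted p = 0.582). PLK2, a stress-induced kinase, went from 27.7 ± 8.89 to 131 ± 40.9 FPKM (log2 change 2.20 ± 0.41, adjusted p = 0.000757), TP53INP1 rose by 0.91, and BAX (-1.27) and FDXR (-1.78) fell. Fluoropyrimidine and nucleotide metabolism had 1 of 25 members rising and 10 falling (alone 1 and 10, adjusted p = 0.122). The thymidine salvage kinase TK1 (-1.82), SHMT2 (-1.68) and FPGS (-1.70) fell. DNA replication had 0 of 33 members rising and 9 falling (alone 0 and 9, adjusted p = 0.288), led by E2F1 (-1.44) and POLD1 (-1.87). DNA repair had 13 of 33 members rising and 2 falling (alone 13 and 2, adjusted p = 0.0851), led by the kinase ATM (1.72). Mitosis genes went both ways, with 12 of 31 members rising and 7 falling (alone 12 and 7, adjusted p = 0.497). BUB1B rose by 1.5 and CDC20 had a change of -1.64. NF-kB and inflammatory cytokines had 10 of 22 members rising and 1 falling (alone 10 and 3, adjusted p = 0.0641). Among those rising were the chemokines CCL20 (1.89) and CXCL10 (1.10). The KDM5 family and H3K4 methylation machinery had 9 of 27 members rising and 2 falling (alone 9 and 2, adjusted p = 0.288), KMT2C rising (1.71) and MEN1 falling (-1.03). Epithelial-mesenchymal transition had 8 of 21 members rising and 2 falling (alone 8 and 2, adjusted p = 0.165), with tenascin TNC (1.34) and MMP7 (1.36) higher. Epithelial identity had 4 of 23 members rising and 10 falling (alone 6 and 11, adjusted p = 0.366), with KRT8 (-1.87) and LGALS4 (-2.34) lower. Hypoxia response gave 5 of 24 members rising and 7 falling (alone 6 and 7, adjusted p = 0.754), the carbonic anhydrase CA9 falling (-2.78). Drug efflux and detoxification had 4 of 25 members rising and 9 falling (alone 4 and 9, adjusted p = 0.582). The aldo-keto reductase AKR1B10 (-1.64) and NQO1 (-1.65) fell.

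In the same comparison, ribosome biogenesis had 4 of 32 members rising and 13 falling (alone 4 and 13, adjusted p = 0.3). Immediate early genes had 0 of 18 members rising and 8 falling (alone 0 and 8, adjusted p = 0.122). The unfolded protein and integrated stress response had 4 of 27 members rising and 11 falling (alone 5 and 11, adjusted p = 0.354). Heat shock response had 1 of 16 members rising and 5 falling (alone 1 and 5, adjusted p = 0.507). Apoptosis regulators had 7 of 25 members rising and 7 falling (alone 7 and 7, adjusted p = 0.775). Antigen presentation had 4 of 19 members rising and 5 falling (alone 4 and 5, adjusted p = 0.882). Wnt targets and intestinal stem cell genes had 7 of 21 members rising and 3 falling (alone 7 and 3, adjusted p = 0.754). Replication-dependent histones had 1 of 15 members rising and 2 falling (alone 1 and 2, adjusted p = 0.928). Cancer-testis and germline genes had 1 of 5 members rising and 0 falling (alone 1 and 0, adjusted p = 0.882). Median, mean and test differed in sign for 6 of these lists and those above: ribosome biogenesis (median 0.05, mean -0.26, test down), drug efflux (0.11, -0.25, down), apoptosis regulators (0.31, -0.04, up), antigen presentation (0.04, -0.12, down), cancer-testis genes (-0.03, 0.16, up) and histones (0.07, -0.11, down). Mitochondrially encoded mRNAs had 0 of 13 members rising and 4 falling (alone 0 and 1, adjusted p = 0.122). Abundant structural noncoding RNAs had 2 of 15 members rising and 6 falling (alone 2 and 7, adjusted p = 0.122), NEAT1 rising (2.22). Markers of cells other than the tumour line were also counted. Fibroblast and matrix markers had 0 of 10 members rising and 3 falling (alone 0 and 1, adjusted p = 0.497). Endothelial markers had 0 of 5 members rising and 3 falling (alone 1 and 4, adjusted p = 0.206). Macrophage and leukocyte markers had 0 of 7 members rising and 2 falling (alone 0 and 1, adjusted p = 0.871). Skeletal muscle markers had 1 of 10 members rising and 3 falling (alone 1 and 3, adjusted p = 0.538). Adipocyte and erythroid markers had 0 of 8 members rising and 3 falling (alone 0 and 3, adjusted p = 0.122). Skin epidermis markers had 0 of 6 members rising and 2 falling (alone 0 and 2, adjusted p = 0.451).

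For JB-157 and JB-161 the question was whether either alone shifted the tumours' transcripts. RNA5SP392, a 5S ribosomal RNA pseudogene that may share reads with other 5S copies, was the single gene past the threshold in each comparison with control. It was listed at 0 in the 5 controls and the 4 5-FU libraries, at 16.3, 24.0, 22.9, 22.1 and 41.8 FPKM in JB-157 1 to 5 and at 9.51, 9.77, 28.7, 141 and 61.7 in JB-161 1 to 5 (limma adjusted p = 0.042 and 0.0151). The next genes did not pass. For JB-157 the lowest unadjusted p among named genes belonged to SMARCD3, a chromatin remodelling subunit, at 1.11 ± 0.594 against 4.03 ± 0.874 FPKM (log2 change -1.28 ± 0.25, n = 5 each, limma adjusted p = 0.209). GATA6-AS1 (-0.96, adjusted p = 0.581), HNRNPCP1 (0.69) and RHEBP2 (0.56, both adjusted p = 0.643) followed. RNA5S6 was listed at 0 in the 5 JB-157 libraries. For JB-161 they were WASH5P (-1.88 ± 0.42, adjusted p = 0.773), RPL37P1 (-1.75), GATA6-AS1 (-0.83), the splicing factor SF3B1 (0.65, 129.5 ± 16.5 against 82.6 ± 14.1 FPKM) and RDH14 (0.70, adjusted p = 0.983). At an unadjusted p under 0.05 there were 970 genes for JB-157 and 690 for JB-161. Both calls lay near the threshold: with one library left out, the adjusted p of RNA5SP392 ran from 0.0876 to 0.24 for JB-157 and from 0.00855 to 0.0991 for JB-161, although all 10 inhibitor libraries lay above all 5 controls. For JB-157 no gene passed without any one library except control 5, and 1 other gene passed without that. For JB-161 none passed without each of controls 1 to 5, JB-161 4 or JB-161 5, 1 passed without JB-161 1 or 2 and 2 without JB-161 3. The 95% interval of the log2 change stayed under 1 in size, which low genes meet easily, for 85.4% of genes under JB-157 and 85.2% under JB-161.

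As lists, ribosomal protein genes were higher under JB-157 (median 0.23, 0.23 with TPM, camera adjusted p = 0.00029, but 0.995 with an estimated correlation) and none of the 49 passed singly, RPL11 having a log2 change of 0.60 (adjusted p = 0.81). Under JB-161, 8 lists passed camera with the preset correlation and no member passed singly or adjusted over the list alone. The hypoxia response list was lower (median -0.24, adjusted p = 0.000453, but 0.801 with an estimated correlation), with PFKFB4 at -0.72 and HILPDA at -0.37. So were glycolysis (median -0.21, adjusted p = 0.0159, but 0.921 with an estimated correlation) and the KDM5 and H3K4 methylation list (median -0.19, adjusted p = 0.00471, but 0.801 with an estimated correlation), CXXC1 at -0.44. The 5 endothelial markers (median -0.37, adjusted p = 0.048, but 0.801 with an estimated correlation) were lower too, MMRN2 at -0.41. Ribosomal proteins (median 0.14, adjusted p = 0.00191, but 0.921 with an estimated correlation) and oxidative phosphorylation (median 0.17, adjusted p = 0.0399, but 0.921 with an estimated correlation) were higher. Mitosis (median 0.11, adjusted p = 0.048, but 0.921 with an estimated correlation), CDK1 at 0.53, and interferon response (median 0.15, adjusted p = 0.048, but 0.921 with an estimated correlation), IFIT5 at 0.36, were higher too. Leaving out one library ended the call (here and later with the highest camera adjusted p, and the number of such libraries if above 2) for JB-157 of ribosomal proteins without control 5 (0.272). For JB-161 it ended each of the 8: the KDM5 list without control 5 or JB-161 4 (0.0982), mitosis (6 libraries, 0.483), interferon response (7 libraries, 0.251), hypoxia response without JB-161 4 (0.0675), glycolysis (3 libraries, 0.377), oxidative phosphorylation (5 libraries, 0.489), ribosomal proteins without control 5 or JB-161 4 (0.281) and endothelial markers (8 libraries, 0.193).

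JB-157 and JB-161 were then set against each other, since they are labelled with the same target and were given at the same dose and days. No gene differed (limma, 0 of 17628 at adjusted p under 0.05, 423 at unadjusted p under 0.05). The 95% interval of the log2 difference stayed under 1 in size for 87.4% of genes. The gene nearest to passing was ARHGEF37, at 1.62 ± 0.57 against 0.491 ± 0.147 FPKM (log2 difference 0.79 ± 0.16, n = 5 each, adjusted p = 0.517). TSSK3 (1.07), FTLP3 (0.77), BUB1B-PAK6 (-0.90), SOCS2-AS1 (-0.55) and CATIP-AS1 (-0.68) came next, each with an adjusted p of 1.00. Without JB-161 3, 2 genes passed. As a list, hypoxia response was higher in JB-157 than in JB-161 (median 0.37, 0.37 with TPM, camera adjusted p = 1.1e-07, but 0.445 with an estimated correlation). The lipid droplet protein HILPDA had a log2 difference of 0.54 ± 0.16 and the pyruvate dehydrogenase kinase PDK1 one of 0.68. Enterocyte differentiation (median 0.20, 0.20 with TPM, camera adjusted p = 0.000995, but 0.239 with an estimated correlation), FABP1 at 0.47, was higher too. So was glycolysis (median 0.16, 0.18 with TPM, camera adjusted p = 0.0335, but 0.91 with an estimated correlation), PGK1 at 0.58. Mitochondrially encoded mRNAs (median -0.51, -0.49 with TPM, camera adjusted p = 0.000995, but 0.91 with an estimated correlation), MT-CO1 at -0.75, were lower. None of these members passed singly. With one library left out, calls ended for glycolysis (5 libraries, 0.366) and mitochondrial mRNAs (3 libraries, 0.576). In an exact 2-sided permutation test of list scores over the 252 arrangements of 5 against 5, hypoxia response differed by 0.36 (p = 0.103) and the smallest p over the 36 lists was 0.0397 (adjusted p = 0.653). Fold changes against control correlated across genes between the compounds (r = 0.637, covariance 0.0534, 73.6% of genes with the same sign). Genes are not independent and the controls are shared, however. Unchanged groups simulated against these controls gave r = 0.469 (95% range -0.215 to 0.876), a covariance of 0.0501 and 66.4% in 1000 simulations. With the 5 controls split between the comparisons, the median r over 20 assignments was -0.022 (-0.220 to 0.257).

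JB-157 together with 5-FU was compared with control. FABP1 was at 3.70 ± 0.931 FPKM against 14.6 ± 4.34 (log2 change -1.71 ± 0.23, limma adjusted p = 0.000486, n = 5 each), and AKR1B10 fell by 2.00 (adjusted p = 0.000486). The nuclear receptor NR0B2 fell by 2.27, REG4 by 2.69, PHGR1 by 2.97 and RNU2-2P by 4.18. TM4SF5 (-2.31), ARHGDIG (-2.30) and CLIC3 (-2.22) fell as well. CPVL, a serine carboxypeptidase homologue, rose from 1.51 ± 0.567 to 6.23 ± 1.16 FPKM (log2 change 1.54 ± 0.23, adjusted p = 0.00162). So did SPTSSB (1.88), the matrix protease MMP7 (1.57), CNBD2 (1.57), PLK2 (1.49), the lipoprotein APOE (1.47), CCL20 (1.42) and IFIT1 (1.38). In total 2299 genes passed, 376 higher and 1923 lower, and after rescaling to TPM, which moved the all-gene median by 0.50, 4885 passed with 4499 higher and 386 lower. The count depended on single libraries. It was 135, 166, 991, 66 and 3977 without controls 1 to 5, and 94, 1479, 69, 4842 and 83 without JB-157+5-FU 1 to 5. With log2 total FPKM as a covariate 27 genes passed, 13 of them among the 2299, whose median log2 change went from a size of 1.02 to 0.29 and whose median standard error went from 0.29 to 0.21.

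Sterol synthesis was among the lists that fell: 0 of 25 rose, 15 fell and 10 did not pass (0 and 15 adjusted over the list alone, median -0.81, -0.49 with TPM, camera adjusted p = 2.07e-07, but 0.565 with an estimated correlation). MVD (-1.86) and DHCR7 (-1.58) were among them. Of ribosomal proteins, 0 of 49 rose, 16 fell and 33 did not pass (0 and 29 adjusted over the list alone, median -0.83, -0.50 with TPM, camera adjusted p = 4.54e-09, but 0.743 with an estimated correlation). For oxidative phosphorylation, 0 of 30 rose, 7 fell and 23 did not pass (0 and 19 adjusted over the list alone, median -0.70, -0.37 with TPM, camera adjusted p = 3.09e-05, but 0.743 with an estimated correlation), NDUFA9 falling by 0.92. In the goblet and secretory list 0 of 20 rose, 6 fell and 14 did not pass (0 and 8 adjusted over the list alone, median -0.58, -0.33 with TPM, camera adjusted p = 0.00461, but 0.743 with an estimated correlation). In enterocyte differentiation 0 of 22 rose, 7 fell and 15 did not pass (0 and 7 adjusted over the list alone, median -0.61, camera adjusted p = 0.0236, but 0.565 with an estimated correlation), where the aminopeptidase ANPEP had -1.19. Glycolysis genes had the same direction: 0 of 20 rose, 5 fell and 15 did not pass (0 and 7 adjusted over the list alone, median -0.43, -0.10 with TPM, camera adjusted p = 0.0266, but 0.809 with an estimated correlation). Interferon response was higher: 6 of 36 rose, 0 fell and 30 did not pass (14 and 3 adjusted over the list alone, median 0.54, camera adjusted p = 3.09e-05, but 0.601 with an estimated correlation), IFI44 rising by 1.10. Among Wnt targets and intestinal stem cell genes, 2 of 21 rose, 0 fell and 19 did not pass (4 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 0.0416, but 0.565 with an estimated correlation), SOX9 (0.54) and NKD1 (0.61) rising. In epithelial-mesenchymal transition, 3 of 21 rose, 1 fell and 17 did not pass (3 and 1 adjusted over the list alone, median 0.31, 0.11 with TPM, camera adjusted p = 0.0483, but 0.565 with an estimated correlation), TNC (1.27) and TGFBI (0.79) rising. Leaving out one library ended the call of glycolysis (3 libraries, 0.0871), Wnt targets (5 libraries, 0.109), enterocyte differentiation without JB-157+5-FU 4 (0.0894) and epithelial-mesenchymal transition (5 libraries, 0.109).

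For JB-161 together with 5-FU against control, GATA6-AS1, an antisense neighbour of the endoderm factor GATA6, went from 18.1 ± 8.87 to 5.38 ± 1.06 FPKM (log2 change -1.49 ± 0.23, limma adjusted p = 0.00673, n = 5 each). A transcript with a clone name, picked after its values were seen, also fell (-1.06, adjusted p = 0.033). These were the 2 genes that passed, while 5244 had an unadjusted p under 0.05. AGO4, an Argonaute protein (1.47), FAM133B (1.37), TNC (1.14), TMEM150B (-1.13) and CBLN3 (-0.88) did not pass, at an adjusted p of 0.068 each. REG4 was at 219 ± 235 FPKM (log2 change -2.27 ± 0.46, adjusted p = 0.068), below each control in 4 of the 5 libraries. Without JB-161+5-FU 1, 5466 genes passed, without control 5 3263, without JB-161+5-FU 5 none, without any one of controls 2 to 4, JB-161+5-FU 2 or 4 1 gene, and without control 1 or JB-161+5-FU 3 2 genes. Lists past the camera threshold numbered 6 and none held a member past the threshold over all genes. Goblet and secretory (median -0.67, adjusted p = 0.000348), ribosomal proteins (median -0.67, -0.38 with TPM, adjusted p = 8.58e-06), oxidative phosphorylation (median -0.49, -0.21 with TPM, adjusted p = 0.00133) and sterol synthesis genes (median -0.47, -0.20 with TPM, adjusted p = 0.0217) were lower, each with an adjusted p of 0.846 with an estimated correlation. Adjusted over the list alone, 7, 15, 6 and 10 of their members fell and 0, 0, 0 and 1 rose. Abundant structural noncoding RNAs were lower (median -1.37, adjusted p = 0.021, but 0.846 with an estimated correlation) with 4 such falls. DNA repair was higher (median 0.37, adjusted p = 0.021, but 0.846 with an estimated correlation) with none, NBN at 0.75. With one library left out, the call ended for DNA repair without control 5 or JB-161+5-FU 4 (0.0615), sterol synthesis without control 5 or JB-161+5-FU 1 (0.129) and structural noncoding RNAs without control 1 (0.162).

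**Figure D3:**
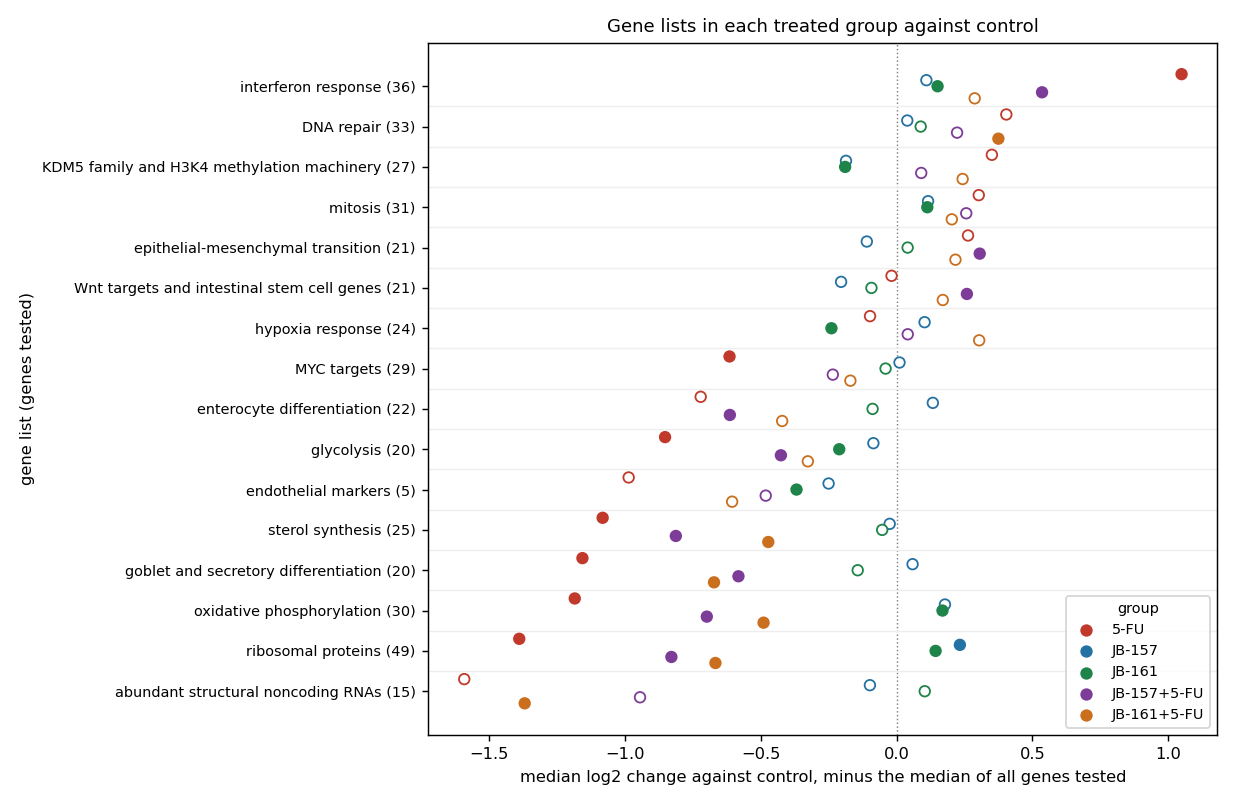
Median log2 change of each gene list against control, minus the median of all genes tested, for the lists past the camera threshold in at least 1 of the 5 comparisons shown. Colours are groups and filled points have a camera adjusted p under 0.05 with the preset correlation; none keeps it with an estimated correlation, and the sterol synthesis list lies at -1.08 for 5-FU, -0.81 for JB-157+5-FU and -0.47 for JB-161+5-FU.

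Each combination was next compared with 5-FU alone, to ask what the inhibitor added. ZBTB43, a zinc finger factor, was lower with either inhibitor. It was at 1.61 ± 0.629 FPKM in JB-157+5-FU and 1.70 ± 0.799 in JB-161+5-FU against 6.26 ± 0.947 in 5-FU (log2 change -1.51 ± 0.29 and -1.48 ± 0.29, limma adjusted p = 0.0373 and 0.045, n = 5, 5 and 4). With JB-157, 10 genes fell and none rose, among them FRMD4A (-0.94) and BIVM-ERCC5 (-0.71), a readthrough locus that shares reads with its parts, and the other 7 have clone names. Not past the threshold were the potassium channel KCNN4 (0.89, adjusted p = 0.125), ASRGL1 (0.76), XAF1 (-1.35, adjusted p = 0.134) and REG4 (1.29, adjusted p = 0.35). With JB-161, 29 genes passed, 1 higher and 28 lower. HOPX rose from 2.95 ± 2.05 to 8.06 ± 1.72 FPKM (log2 change 1.30 ± 0.28, adjusted p = 0.045), and XAF1 fell from 4.05 ± 3.66 to 0.388 ± 0.233 (-1.56 ± 0.32, adjusted p = 0.045). DFFBP1 (-0.94), GLUD1P3 (-0.87), RN7SL381P (-1.46) and RN7SKP287 (-1.22), all pseudogenes that may share reads with their parents, fell. RNU2-11P and RN7SL145P were listed at 0 in the 5 JB-161+5-FU libraries and at 0, 2.17, 2.29 and 3.79 and 0.555, 2.57, 1.09 and 1.35 FPKM in the 4 5-FU libraries. RSAD2 (-0.89, adjusted p = 0.0515) and STAT2 (-1.07, adjusted p = 0.0519) came close. Rescaling to TPM, which moved the all-gene medians by -0.27 and -0.38, gave 7 higher and 103 lower genes with JB-157 and 4 and 674 with JB-161. With JB-157 the count was 9, 3, 104 and 0 without 5-FU 1 to 4, and 12, 2, 0, 0 and 59 without JB-157+5-FU 1 to 5. With JB-161 it was 11, 24, 434 and 0 without 5-FU 1 to 4, and 0, 7, 86, 10 and 0 without JB-161+5-FU 1 to 5. The covariate left 2 and 0 genes: among the 10 and 29 the median size of the change went from 0.91 to 0.78 and from 0.94 to 0.78, and the median standard error from 0.17 to 0.16 and from 0.20 to 0.19.

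Interferon response was lower in both combinations than in 5-FU alone, and both comparisons share the same 4 5-FU libraries. With JB-161, 0 of 36 rose, 1 fell and 35 did not pass (0 and 21 adjusted over the list alone, median -0.66, camera adjusted p = 3.26e-14, but 0.274 with an estimated correlation). With JB-157, 0 of 36 rose, 0 fell and 36 did not pass (0 and 7 adjusted over the list alone, median -0.49, camera adjusted p = 5.64e-06, but 0.489 with an estimated correlation), DDX58 at -0.84 (adjusted p = 0.235). Its scores were -0.02, 0.77, 0.22 and 1.30 in 5-FU 1 to 4, -0.02 to 0.23 in JB-157+5-FU and -0.21 to -0.06 in JB-161+5-FU, so 5-FU 1 and 3 lay within the range of JB-157+5-FU. Without 5-FU 4 the list did not pass with JB-157 (median -0.23, camera adjusted p = 0.0602) and had a median of -0.47 with JB-161. NF-kB and inflammatory cytokines were lower with JB-161, where 0 of 22 rose, 0 fell and 22 did not pass (0 and 10 adjusted over the list alone, median -0.44, camera adjusted p = 1.74e-05, but 0.331 with an estimated correlation), CXCL8 at -0.99 and CCL20 at -1.28. The NF-kB score was 1.14 in 5-FU 4 and 0.24, 0.12 and -0.09 in 5-FU 1 to 3, and without 5-FU 4 the median was -0.27 (camera adjusted p = 0.00955). Higher lists held no member past the threshold over all genes. In JB-157+5-FU they were ribosomal proteins (median 0.55, adjusted p = 1.49e-09), goblet and secretory (median 0.48, adjusted p = 6.27e-06) and oxidative phosphorylation (median 0.45, adjusted p = 1.21e-05). With them went MYC targets (median 0.32, adjusted p = 0.00139), glycolysis (median 0.41, adjusted p = 0.00182), DNA replication (median 0.30, adjusted p = 0.00197) and immediate early genes (median 0.29, adjusted p = 0.0141), each of the 7 at an adjusted p of 0.489 with an estimated correlation. In JB-161+5-FU they were ribosomal proteins (median 0.72, adjusted p = 1.87e-14, but 0.437 with an estimated correlation), oxidative phosphorylation (median 0.62, adjusted p = 8.42e-08, but 0.437 with an estimated correlation) and sterol synthesis (median 0.50, adjusted p = 8.56e-07, but 0.331 with an estimated correlation), with NSDHL at 0.81. The others were MYC targets (median 0.40, adjusted p = 8.33e-06, but 0.331 with an estimated correlation), glycolysis (median 0.50, adjusted p = 1.74e-05, but 0.437 with an estimated correlation) and goblet and secretory genes (median 0.51, adjusted p = 0.000285, but 0.455 with an estimated correlation), 3 of which rose when adjusted over the list alone. A further 6 lists, with camera adjusted p from 0.00149 to 0.0409, were DNA replication, the unfolded protein and integrated stress response, hypoxia response, ribosome biogenesis (median 0.11, turned to -0.03 with TPM), mitochondrially encoded mRNAs and fluoropyrimidine metabolism, and none of them passed with an estimated correlation (lowest adjusted p = 0.331 with an estimated correlation). With JB-157 and one library left out, the call ended for DNA replication without 5-FU 1 or 4 (0.203), glycolysis without 5-FU 4 (0.0939), immediate early genes without 5-FU 3 or 4 (0.0798) and MYC targets without 5-FU 1 or 4 (0.0698). With JB-161 it ended for fluoropyrimidine metabolism (5 libraries, 0.235), DNA replication without 5-FU 1 (0.135), hypoxia response without 5-FU 4 or JB-161+5-FU 2 (0.245), ribosome biogenesis without 5-FU 1 or 4 (0.153) and mitochondrial mRNAs without 5-FU 2 or JB-161+5-FU 1 (0.105).

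Each combination was set against its inhibitor alone, but with doses unstated and totals unequal this does not isolate 5-FU. In JB-157+5-FU, FABP1 fell from 19.3 ± 6.02 to 3.70 ± 0.931 FPKM (log2 change -2.09 ± 0.23, limma adjusted p = 1.51e-05, n = 5 each) and AKR1B10 from 108 ± 23.0 to 22.9 ± 3.08 (-2.17 ± 0.27, adjusted p = 0.000105). AKR1C1 (-1.09), MVD (-1.86), REG4 (-2.51), PHGR1 (-3.18), ARHGDIG (-2.56), NME7 (-2.95), LDLRAD2 (-3.40), C6orf47-AS1 (-2.56) and MDM2 (-1.14), the ubiquitin ligase of p53, also fell. PLK2 (1.66), GOLGA8B (2.33), RNF185-AS1 (1.84), SPTSSB (1.80), CSAD (1.69), PAN2 (1.68), ARGLU1 (1.61), the death receptor TNFRSF10B (0.71) and the ERK phosphatase DUSP6 (1.19) rose. RNA5SP392 was listed at 0, 0, 4.33, 0 and 0 FPKM in JB-157+5-FU 1 to 5 and at 32.8, 0, 0, 0 and 6.97 in JB-161+5-FU 1 to 5 (JB-157+5-FU against JB-157, adjusted p = 0.00857). Of 2394 genes that passed, 632 were higher and 1762 lower, and TPM, moving the all-gene median by 0.53, gave 6018 and 479. Leaving out JB-157 1 to 5 gave 1389, 166, 126, 3209 and 241, and JB-157+5-FU 1 to 5 gave 78, 1392, 73, 4649 and 102. The covariate left 87, 29 of them among the 2394, whose median size of change went from 1.01 to 0.24 and median standard error from 0.30 to 0.21.

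By list, sterol synthesis was lower: 0 of 25 rose, 12 fell and 13 did not pass (0 and 15 adjusted over the list alone, median -0.65, -0.35 with TPM, camera adjusted p = 4.14e-07, but 0.235 with an estimated correlation). For ribosomal proteins, 0 of 49 rose, 39 fell and 10 did not pass (0 and 45 adjusted over the list alone, median -1.03, camera adjusted p = 2.4e-16, but 0.463 with an estimated correlation). For oxidative phosphorylation, 0 of 30 rose, 16 fell and 14 did not pass (0 and 21 adjusted over the list alone, median -0.82, -0.50 with TPM, camera adjusted p = 1.51e-07, but 0.463 with an estimated correlation). For enterocyte differentiation, 0 of 22 rose, 6 fell and 16 did not pass (0 and 11 adjusted over the list alone, median -0.54, camera adjusted p = 0.00452, but 0.235 with an estimated correlation). Goblet and secretory (median -0.49, adjusted p = 0.00242, but 0.743 with an estimated correlation) and glycolysis genes (median -0.31, 0.01 with TPM, adjusted p = 0.0451, but 0.814 with an estimated correlation) were lower too. In them, 7 of 20 and 3 of 20 members fell (8 and 6 adjusted over the list alone). Of Wnt targets and intestinal stem cell genes, 6 of 21 rose, 0 fell and 15 did not pass (6 and 0 adjusted over the list alone, median 0.30, 0.46 with TPM, camera adjusted p = 0.00147, but 0.235 with an estimated correlation), with the negative regulator AXIN2 at 1.07 and EPHB2 at 0.55. For epithelial-mesenchymal transition, 7 of 21 rose, 1 fell and 13 did not pass (9 and 3 adjusted over the list alone, median 0.45, camera adjusted p = 0.00308, but 0.235 with an estimated correlation), TNC at 1.38. Interferon response (median 0.41, adjusted p = 0.00188, but 0.743 with an estimated correlation) and the KDM5 and H3K4 methylation list (median 0.26, 0.44 with TPM, adjusted p = 0.0162, but 0.661 with an estimated correlation) were higher. Of their members, 3 of 36 and 1 of 27 rose (6 and 0 adjusted over the list alone, where 1 interferon member also fell), IFIT1 at 0.90 and KMT2D at 0.90. The call ended with one left out for glycolysis (5 libraries, 0.12).

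In JB-161+5-FU against JB-161 no gene passed (limma, 0 of 17628, 5244 at unadjusted p under 0.05), but without JB-161 3 5342 did and without JB-161+5-FU 1 5600. TNC was at 3.72 ± 2.37 against 0.823 ± 0.179 FPKM (log2 change 1.24 ± 0.25, adjusted p = 0.119), the acetyltransferase CREBBP at 0.79, RNF111 at 1.20, HOPX at -1.28, AKR1B10 at -1.24, SSTR5-AS1 at -1.30 and REG4 at -1.91. Lists that passed camera without single members were, on the lower side, ribosomal proteins (median -0.88, -0.58 with TPM, adjusted p = 4.65e-12, but 0.748 with an estimated correlation, 35 of 49 falling adjusted over the list alone) and oxidative phosphorylation (median -0.72, -0.43 with TPM, adjusted p = 9.89e-07, but 0.748 with an estimated correlation, 22 of 30). With them were goblet and secretory (median -0.48, -0.24 with TPM, adjusted p = 0.0024, but 0.889 with an estimated correlation, 5 of 20) and structural noncoding RNAs (median -1.60, adjusted p = 0.00449, but 0.748 with an estimated correlation, 6 of 15). On the higher side were hypoxia response (median 0.59, adjusted p = 0.000126, but 0.748 with an estimated correlation, 9 of 24 rising adjusted over the list alone), the demethylase KDM3A at 1.24 and VEGFA at 1.12. The KDM5 and H3K4 methylation list was higher too (median 0.32, 0.49 with TPM, adjusted p = 0.0024, but 0.748 with an estimated correlation, 11 of 27 rising adjusted over the list alone), KMT2A at 1.07.

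No single gene differed between the combinations (limma, 0 of 17628, 313 at unadjusted p under 0.05). In 88.8% of genes the 95% log2 interval stayed under 1 in size. CPVL was at 6.23 ± 1.16 FPKM with JB-157 and 2.90 ± 0.736 with JB-161 (log2 difference 0.89 ± 0.23, n = 5 each, adjusted p = 1.00) and AKR1B10 at 22.9 ± 3.08 and 47.8 ± 20.8 (-0.95 ± 0.27). FABP1 was at 3.70 ± 0.931 and 6.94 ± 1.98 (-0.75 ± 0.23), and AKR1B10P1 (-0.71), C8orf31 (0.43) and GPX8 (0.56) followed. As a list, sterol synthesis was lower with JB-157 (median -0.35, adjusted p = 5.36e-13, but 0.109 with an estimated correlation). Interferon response (median 0.25, adjusted p = 8.74e-10, but 0.312 with an estimated correlation), IFITM1 at 1.17, and NF-kB and inflammatory cytokines (median 0.22, adjusted p = 2.97e-05, but 0.312 with an estimated correlation) were higher with JB-157. So were antigen presentation (median 0.21, adjusted p = 0.0209, but 0.426 with an estimated correlation) and Wnt targets (median 0.12, adjusted p = 0.0391, but 0.426 with an estimated correlation). Hypoxia response (median -0.19, adjusted p = 0.000443, but 0.459 with an estimated correlation), ribosomal proteins (median -0.14, adjusted p = 0.00101, but 0.648 with an estimated correlation) and ribosome biogenesis (median -0.14, adjusted p = 0.00963, but 0.459 with an estimated correlation) were lower. MYC targets (median -0.14, adjusted p = 0.0313, but 0.587 with an estimated correlation), the unfolded protein response (median -0.11, -0.07 with TPM, adjusted p = 0.0241, but 0.426 with an estimated correlation), oxidative phosphorylation (median -0.09, -0.05 with TPM, adjusted p = 0.0391, but 0.648 with an estimated correlation) and glycolysis (median -0.12, adjusted p = 0.0391, but 0.648 with an estimated correlation) were lower too. No member of these lists passed singly or adjusted over the list alone. In the exact 2-sided permutation test over 252 arrangements, the list scores differed by -0.38 for sterol synthesis, 0.28 for interferon response and 0.23 for NF-kB, each at the smallest p the design allows (p = 0.00794, adjusted p = 0.0952 over 36 lists), with every JB-157+5-FU library on one side of every JB-161+5-FU library. One library left out ended the call of antigen presentation (4 libraries, 0.199), hypoxia response without JB-161+5-FU 2 (0.54), glycolysis (5 libraries, 0.665), oxidative phosphorylation (4 libraries, 0.423), the unfolded protein response (3 libraries, 0.609), Wnt targets (7 libraries, 0.351), ribosomal proteins (3 libraries, 0.306) and MYC targets (5 libraries, 0.225).

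**Figure D4:**
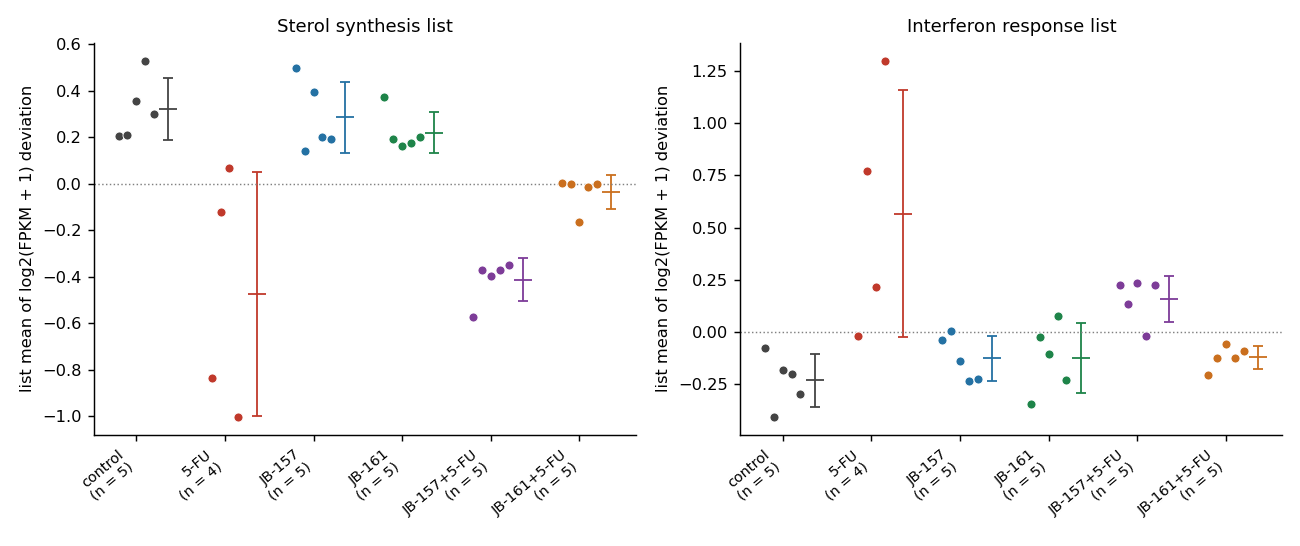
Mean log2(FPKM + 1) deviation of the sterol synthesis list (left) and the interferon response list (right) in each library, by group. Points are libraries and the bar beside them is the mean with its SD; sterol synthesis averages -0.41 ± 0.09 in JB-157+5-FU and -0.03 ± 0.07 in JB-161+5-FU, and interferon response spreads from -0.02 to 1.30 over the 4 5-FU libraries.

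Whether inhibitor and 5-FU acted other than additively was tested as an interaction. No gene passed for either compound (limma, 0 of 17628 each, 1441 and 1368 at unadjusted p under 0.05). For JB-157 the named genes were the testis kinase gene TSSK3 (-2.15 ± 0.41, adjusted p = 0.236), the death ligand TNFSF10 (-1.61), HNRNPCP1 (-1.09), KCNN4 (1.06), SIAH2 (0.81) and RENBP (0.94). For JB-161 they were DNAJC3-AS1 (-1.54 ± 0.32), GLUD1P3 (-1.05), HIST1H2AK (-1.01), HILPDA (0.92) and CSPG4 (1.60), at an adjusted p of 0.525. A single gene passed for JB-157 without 5-FU 3 or without JB-157 2, and for JB-161 without 5-FU 1. Both interactions rest on the same control and 5-FU libraries. Interferon response was lower in the combination than the sum of the single effects by 0.51 for JB-157 (median -0.51, adjusted p = 5.18e-06, but 0.59 with an estimated correlation) and lower for JB-161 too (median -0.87, adjusted p = 5.28e-15, but 0.211 with an estimated correlation). Without 5-FU 4 the medians were -0.31 and -0.68, and without 5-FU 1 they were -0.79 and -0.99. For JB-161, 20 of 36 members fell adjusted over the list alone, MX1 at -1.52 and IFIT1 at -1.57. NF-kB and inflammatory cytokines were lower for JB-161 (median -0.33, adjusted p = 0.000183, but 0.226 with an estimated correlation), 4 of 22 falling adjusted over the list alone. Higher for JB-161 were glycolysis (median 0.69, adjusted p = 3.02e-07, but 0.226 with an estimated correlation) and sterol synthesis (median 0.58, adjusted p = 3.55e-06, but 0.226 with an estimated correlation), MVD at 1.24. So were hypoxia response (median 0.62, adjusted p = 4.65e-06, but 0.258 with an estimated correlation), ribosomal proteins (median 0.58, adjusted p = 8.67e-06, but 0.468 with an estimated correlation), MYC targets (median 0.46, adjusted p = 1.52e-05, but 0.226 with an estimated correlation) and goblet and secretory genes (median 0.62, adjusted p = 0.000132, but 0.375 with an estimated correlation), 2 members of the hypoxia and 2 of the goblet list rising when adjusted over the list alone. A further 9 lists were higher with camera adjusted p from 0.000637 to 0.0487 (lowest adjusted p = 0.226 with an estimated correlation). Among them were the endothelial (median 0.62, adjusted p = 0.0487) and the adipocyte and erythroid markers (median 0.38, adjusted p = 0.0487, both 0.226 with an estimated correlation). These are human genes and do not measure the mouse host cells. For JB-157, 11 lists besides interferon response passed and were higher, from immediate early and goblet genes (both camera adjusted p = 0.00175) to mitochondrially encoded mRNAs (0.0455), with a lowest adjusted p of 0.59 with an estimated correlation. Endothelial markers were among them (median 0.70, adjusted p = 0.0228, but 0.59 with an estimated correlation). With one library left out, 7 of the 12 lists lost their call for JB-157 and 5 of the 17 for JB-161, of those given with a median only the endothelial and the adipocyte and erythroid markers for JB-161, each without any one of 13 libraries (highest adjusted p = 0.13 and 0.115).

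The labelled target and the other genes fixed in advance were measured in each group. KDM5B, at 202724495 to 202809470 on the minus strand of chromosome 1 in GENCODE release 29 on GRCh38, was at 7.38 ± 0.609 FPKM in control, 6.56 ± 2.53 in JB-157, 5.81 ± 1.06 in JB-161, 11.9 ± 2.70 in 5-FU, 9.96 ± 2.24 in JB-157+5-FU and 10.5 ± 2.69 in JB-161+5-FU. It rose with 5-FU alone (log2 change 0.60 ± 0.23, limma adjusted p = 0.0311) and did not pass in the other comparisons, the lowest adjusted p being 0.0666 for JB-157+5-FU against JB-157 (0.57), beside -0.21 for JB-157 and -0.31 for JB-161 against control. KDM5A also rose with 5-FU (0.87 ± 0.34, adjusted p = 0.0391), while KDM5C (-0.30, adjusted p = 0.228) did not pass. TYMS, the enzyme that 5-FU blocks, was at 72.2 ± 18.4 FPKM in control and 81.4 ± 19.7 in 5-FU (0.18 ± 0.20, adjusted p = 0.493). CDKN1A, a cell cycle inhibitor, fell with 5-FU (-0.86 ± 0.32, adjusted p = 0.0284), as did MYC (-0.58 ± 0.21, adjusted p = 0.0286), and MDM2 (-0.56, adjusted p = 0.211) and the epithelial adhesion gene EPCAM (0.31, adjusted p = 0.308) did not pass. Rescaling to TPM turned the signs of CDKN1A (0.27), MYC (0.58), MDM2 (0.58) and KDM5C (0.84), and the covariate turned those of CDKN1A (0.24) and KDM5A (-0.29).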

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

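All tests weighed here on total FPKM, on the sterol list within strata of total FPKM, on the pooled 5-FU model and on single libraries were chosen after the results were seen, as were the counts of other splits for genes called, except for the interactions and the pooled model; the counts of other splits for lists were chosen before. Chance places a library this far from its group in about 1 in 20 groups, and 96 groups were examined.

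Libraries given 5-FU had lower total FPKM and lower short against long genes. Without mitochondrial RNA and the 100 most abundant genes the total still differed, 0.425 ± 0.105 against 0.671 ± 0.124 (1e6 FPKM, 2-sided permutation p = 7e-05). They do not explain all of the pattern, whose short against long part was not retested. Reads from genomic DNA or unspliced RNA cannot be told apart from it: of 421 olfactory receptor genes 1.66% at most were above 0 in untreated libraries below 1e6 and 2.38% to 5.70% in treated ones below it, but 2 untreated libraries lie there. The share averaged 4.51% in 5-FU, 3.04% in JB-157+5-FU and 2.57% in JB-161+5-FU against 1.19% to 1.43% in the controls, a signal outside the tested genes, and sense intronic rows had a mean deviation of 0.34 in 5-FU and -0.10 in control but -0.15 in JB-161+5-FU 2, which lies below 1e6. RNA quality was not given, and a shift of transcription, decay or length by the drug, or a library effect that follows treatment, stays open and was not tested.

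Genes called between 5-FU and control, 8066, fell to 4 with log2 total FPKM as a covariate, and 5-FU and the trend with total FPKM cannot be told apart for the rest because all 4 5-FU libraries lie below each control in total. For the pooled 5-FU term over all libraries, 10 genes passed with the covariate and 10283 without it: FABP1, AKR1B10, HOPX and NR0B2 lower and EEF1A2, CRABP2, APOE, ZNF385A, PLTP and ZNF467 higher. Without the model CRABP2 (241 ± 116 FPKM in treated against 248 ± 89.0 in other libraries) and ZNF385A (4.33 ± 2.37 against 5.96 ± 2.25) were not higher, and 8 genes, 4 of them among the 10, passed without JB-161+5-FU 1 and 0 without that library and JB-161 3, so this may rest on a few libraries. The trend does not account for the sterol synthesis list, whose score was -0.295 ± 0.331 in the 14 treated and 0.276 ± 0.126 in the 15 others, and differed by -0.47 above and -0.55 below 1e6 (exact permutation within strata, 9555 arrangements, adjusted p = 0.0207 over 36 lists; without JB-161+5-FU 1, adjusted p = 0.0377). Enterocyte differentiation and epithelial-mesenchymal transition passed the same test (adjusted p = 0.0207 and 0.0490). A drug effect on sterol genes is a hypothesis raised by the same data.

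JB-161+5-FU 1 stood apart from its group and lay on the treated side in 0 of 34 genes, not adjusted for total FPKM, that parted all other treated from all other untreated libraries, and in 4 of the 20 genes of smallest p, none past the threshold, in the pooled model fitted without it and JB-161 3. Other libraries with a total across 1e6 from most of their treatment lay across in part: without JB-161+5-FU 1 and the library itself, JB-157+5-FU 4 lay on the treated side in 25 of 335 parting genes, JB-161 3 in 70 of 96 and control 5 in 23 of 55, against 34 of 42 or a higher share in the other treated and 6 of 40 or a lower one in the other untreated. An exchange with JB-161 3 cannot be told apart from this, since parting genes may follow the total, JB-161 3 had 9 of the 20, which did not pass, and the sterol score, by which both libraries lay with their own label (0.16 in JB-161 3), was picked with both in the data. That the tumour received no 5-FU, or that the label is wrong, cannot be told apart from a tumour that did not respond. Its total was 1.74 (others of the group 0.696 to 0.764, in units of 1e6 FPKM), its 100 most abundant genes took 57.8% (42.2% to 45.2%), its short minus long value was 0.52 (-0.47 to -0.37) and its CDKN1A was 45.2 FPKM (17.7 to 20.4).

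Other far values were these. Short minus long was -0.49 in 5-FU 3 (others -0.72 to -0.68) and -0.32 in JB-161 3 (0.43 to 0.64). The sterol list score was 0.37 in JB-161 1 (0.16 to 0.20), -0.57 in JB-157+5-FU 1 (-0.40 to -0.35) and -0.16 in JB-161+5-FU 3 (-0.01 to 0.00). KDM5A was 8.95 FPKM in JB-161 3 (2.05 to 3.05), MDM2 was 114 in control 1 (16.2 to 32.4) and EPCAM was 511 in control 5 (210 to 296). The interferon response list differed between tumours with and without JB-161 in its 5-FU effect, with a median interaction of -0.87 (camera adjusted p = 5.28e-15, but adjusted p = 0.211 with an estimated correlation), and the score in the 5-FU group ran from -0.02 to 1.30.

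Other splits of the same libraries were counted, 100 per comparison with the real one included, and under 5 with as many genes called is the bound for excluding chance, with no allowance for the number of comparisons. In each comparison of groups under it, another split called more genes. Brackets hold the real and the highest other count. As many came from 2 splits for 5-FU (8066, 8210), 2 for JB-157+5-FU (2299, 6796) and 6 for JB-161+5-FU (2, 7662) against control, 5 and 2 for JB-157+5-FU (10, 206) and JB-161+5-FU (29, 264) against 5-FU, and 2 for JB-157+5-FU against JB-157 (2394, 5234). For JB-157 (1, 750) and JB-161 (1, 1116) against control it was 25 and 30. It was 100 where 0 genes were called: JB-161+5-FU against JB-161 (highest other 9027), JB-157 against JB-161 (375), the combinations (75) and the interactions (3344 and 7843). Of the other splits, the one closest to total FPKM gave 8210, 6796, 7662, 206, 5234 and 9027 (0 to 2 in the other 5 comparisons), pointing to a structure along the total. For lists past the threshold it was 78 (7, 16), 92 (1, 12) and 13 (8, 14) for 5-FU, JB-157 and JB-161, 24 (9, 13) and 52 (6, 13) for the combinations against control, 77 (8, 15) and 25 (14, 17) against 5-FU, and 21 (10, 15) and 43 (6, 11) against the inhibitor. It was 52 (4, 13) for the inhibitors, 7 (12, 14) for the combinations and 20 (12, 17) and 1 (17, 15) for the interactions. The last is the smallest number possible, over 13 comparisons, and none of its 17 lists passed with an estimated correlation (lowest adjusted p = 0.211). For the pooled term it was 1 (10, 0).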

How the results depend on the processing

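Fits with log2 total FPKM as a covariate or within libraries above or below 1e6 total FPKM, and list tests and the pooled model with one library left out, were chosen after the data were seen, and all others before. A group named alone is meant against control, and brackets after a list hold its median minus that of all genes. Directions of named genes that passed were kept except where given here, and for each change below the cause was not tested. Depth is unknown, and a log2 change near 1 was recovered in fewer than 50% of simulated genes, so small changes are most limited. A planned test on read counts recovered from FPKM was not run, since FPKM steps depend on gene length, and fits above 1e6 gave no value where the 5-FU group enters, nor fits below 1e6 where the JB-157 group enters. Within these fits 4 groups keep 1 library each, which is assumed to vary like the other groups. With log2 total FPKM as a covariate, genes called were 4 for 5-FU, 2 for JB-157 and JB-157+5-FU vs 5-FU, 27 for JB-157+5-FU, 0 for JB-161+5-FU vs 5-FU, 87 for JB-157+5-FU vs JB-157. Lists past the threshold then were 15 for 5-FU, 2 for JB-157, 13 for JB-157+5-FU vs 5-FU. The sign then turned for CDKN1A (0.241) and KDM5A (-0.295) in 5-FU. The camera direction then turned for oxidative phosphorylation (0.0854) and ribosomal proteins (0.0717) in JB-157+5-FU, oxidative phosphorylation (0.0125) and ribosomal proteins (0.0981) in JB-161+5-FU, the KDM5 list (median 0.0388, sign kept) in JB-157+5-FU vs JB-157, oxidative phosphorylation (0.0194) and ribosomal proteins (median -0.00156, sign kept) in JB-157+5-FU vs JB-161+5-FU, ribosomal proteins (median 0.00742, sign kept) in interaction of JB-157 and 5-FU. In libraries below 1e6 total FPKM alone, genes called were 23 for 5-FU, 8 for JB-161, JB-161+5-FU and interaction of JB-161 and 5-FU, 4 for JB-157+5-FU and JB-161+5-FU vs 5-FU, 1 for JB-157+5-FU vs 5-FU, 10 for JB-161+5-FU vs JB-161. Lists past the threshold then were 11 for 5-FU, 2 for JB-161, 9 for interaction of JB-161 and 5-FU. The sign then was lost for RNA5S6 (0) in 5-FU. The camera direction then turned for oxidative phosphorylation (-0.16) and ribosomal proteins (-0.187) in JB-161, structural noncoding RNAs (0.0583) in JB-161+5-FU, goblet and secretory differentiation (0.127) in JB-161+5-FU vs JB-161. With no filter, genes called were 2 for JB-157, 219 for JB-157+5-FU, 1 for JB-161+5-FU, JB-157 vs JB-161 and interaction of JB-161 and 5-FU, 134 for JB-157+5-FU vs 5-FU, 306 for JB-161+5-FU vs 5-FU, 415 for JB-157+5-FU vs JB-157, 3 for interaction of JB-157 and 5-FU. With TPM scaling, genes called were 0 for JB-157 and JB-161+5-FU, 4885 for JB-157+5-FU, 110 for JB-157+5-FU vs 5-FU, 678 for JB-161+5-FU vs 5-FU, 6497 for JB-157+5-FU vs JB-157. Lists past the threshold then were 13 for 5-FU, 2 for JB-157, 14 for JB-157+5-FU, 12 for JB-161+5-FU vs JB-161, 7 for JB-157 vs JB-161. The sign then turned for CDKN1A (0.266), KDM5C (0.839), MDM2 (0.578), MEN1 (0.0947) and MYC (0.577) in 5-FU. In a fit of only the groups compared, genes called were 2 for JB-157, 1295 for JB-157+5-FU, 0 for JB-161+5-FU, JB-157+5-FU vs 5-FU and JB-161+5-FU vs 5-FU, 1 for JB-157+5-FU vs JB-161+5-FU and interaction of JB-157 and 5-FU. With array weights, genes called were 0 for JB-157, 39 for JB-161, 7618 for JB-157+5-FU, 7888 for JB-161+5-FU, 71 for JB-157+5-FU vs 5-FU, 369 for JB-161+5-FU vs 5-FU, 7906 for JB-157+5-FU vs JB-157, 9852 for JB-161+5-FU vs JB-161, 4 for JB-157+5-FU vs JB-161+5-FU. In libraries above 1e6 total FPKM alone, genes called were 0 for JB-157 and JB-161, 4 for JB-157+5-FU, 7 for JB-161+5-FU, 8 for JB-157+5-FU vs JB-157, 6 for JB-161+5-FU vs JB-161, 3 for JB-157+5-FU vs JB-161+5-FU. Lists past the threshold then were 0 for JB-157, 2 for JB-161+5-FU, 3 for JB-161+5-FU vs JB-161, 4 for JB-157+5-FU vs JB-161+5-FU. The camera direction then turned for DNA repair (-0.0907), oxidative phosphorylation (0.238) and ribosomal proteins (0.354) in JB-161+5-FU, glycolysis (0.0684) in JB-157+5-FU vs JB-157, ribosomal proteins (0.109) in JB-161+5-FU vs JB-161, hypoxia response (0.0339), glycolysis (median -0.0202, sign kept) and the unfolded protein response (0.0996) in JB-157+5-FU vs JB-161+5-FU. With median-ratio scaling or the filter at FPKM 2, genes called were 1 for JB-161+5-FU. With that filter or a pseudocount of 0.1, genes called were 0 for JB-157+5-FU vs 5-FU and JB-161+5-FU vs 5-FU. With an estimated correlation, lists past the threshold were 0 for each comparison that gave a value. With fry, lists past the threshold were 16 for 5-FU, 0 for JB-157, JB-161, JB-157+5-FU vs 5-FU, JB-161+5-FU vs JB-161, JB-157 vs JB-161, JB-157+5-FU vs JB-161+5-FU and interaction of JB-157 and 5-FU, 3 for JB-161+5-FU and JB-161+5-FU vs 5-FU, 1 for interaction of JB-161 and 5-FU. With the covariate and an estimated correlation, lists past the threshold were 1 for JB-157+5-FU and JB-161+5-FU vs JB-161, 0 for each other comparison. In libraries below or above 1e6 with an estimated correlation, lists past the threshold were 0 for each comparison that gave a value. With TPM scaling the camera direction held for each list call but the medians of glycolysis in JB-157+5-FU vs JB-157 (0.01) and ribosome biogenesis in JB-161+5-FU vs 5-FU (-0.03) turned. Genes called ranged, with one library left out, over 6571 to 8767 for 5-FU, 0 to 1 for JB-157, 0 to 2 for JB-161, 66 to 4842 for JB-157+5-FU, 0 to 5466 for JB-161+5-FU, 0 to 104 for JB-157+5-FU vs 5-FU, 0 to 434 for JB-161+5-FU vs 5-FU, 73 to 4649 for JB-157+5-FU vs JB-157, 0 to 5600 for JB-161+5-FU vs JB-161, 0 to 2 for JB-157 vs JB-161, 0 to 0 for JB-157+5-FU vs JB-161+5-FU, 0 to 1 for interaction of JB-157 and 5-FU, 0 to 1 for interaction of JB-161 and 5-FU. Lists past the threshold ranged, with one library left out, over 7 to 11 for 5-FU, 0 to 6 for JB-157, 0 to 11 for JB-161, 7 to 10 for JB-157+5-FU, 4 to 9 for JB-161+5-FU, 3 to 14 for JB-157+5-FU vs 5-FU, 12 to 16 for JB-161+5-FU vs 5-FU, 9 to 12 for JB-157+5-FU vs JB-157, 6 to 9 for JB-161+5-FU vs JB-161, 3 to 6 for JB-157 vs JB-161, 6 to 13 for JB-157+5-FU vs JB-161+5-FU, 5 to 16 for interaction of JB-157 and 5-FU, 14 to 20 for interaction of JB-161 and 5-FU. Of 114 list calls, 49 were lost without at least 1 single library. In the comparison of the combinations with one library left out, oxidative phosphorylation ranged from -0.261 to 0.0986 and ribosomal proteins from -0.349 to 0.109. With the controls split, fold changes of the inhibitors correlated at -0.022.

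With the replicate number as replicate block, genes called were 0 for JB-157 and JB-161, 1 for JB-161+5-FU, 2 for JB-157+5-FU vs 5-FU and JB-161+5-FU vs 5-FU. Libraries of one replicate number did not deviate together (19 of 70 pairs with r above 0.1, median r = -0.01, 5 of 29 libraries closest to their own number), so this replicate block pairs nothing the labels state.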

Other observations

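These values were looked at only after the results were seen. RNA5SP392, the 5S pseudogene at 40331537 to 40331648 on the minus strand of chromosome 15, was listed above 0 in all 10 libraries given an inhibitor alone and in 3 of 10 given a combination, and in none of the 9 others.

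The interferon response score averaged -0.23 ± 0.13 in control, 0.57 ± 0.59 in 5-FU, -0.13 ± 0.11 in JB-157, -0.13 ± 0.17 in JB-161, 0.16 ± 0.11 in JB-157+5-FU and -0.12 ± 0.05 in JB-161+5-FU. The sterol synthesis score averaged 0.32 ± 0.13, -0.47 ± 0.53, 0.29 ± 0.15, 0.22 ± 0.09, -0.41 ± 0.09 and -0.03 ± 0.07 in the same order, and within 5-FU it was -0.84, -0.12, 0.07 and -1.0 in libraries 1 to 4. By correlation over all genes tested, JB-161+5-FU 1 lay closest to JB-161 2 (r = 0.980), JB-161 3 to JB-161+5-FU 4 (r = 0.984) and control 5 to JB-157+5-FU 2 (r = 0.982).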
